A study of Rattus norvegicus with 22 samples.

How the data were processed

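RNA was measured in the livers of rats from 4 groups, 22 libraries in all. Control rats (5 libraries) received a normal diet and 0.9% saline, and Model rats (5 libraries) a high-fat diet and 0.9% saline. The HTJZD group (6 libraries) received the high-fat diet and Huatan Jiangzhuo Decoction, a herbal decoction, at 12.6 g/kg. The PC-AR group (6 libraries) received the high-fat diet and a preparation of Poria cocos and Alismatis Rhizoma, a fungus and a plant rhizome, at 4.54 g/kg. Per the labels, the high-fat diet was given for 4 weeks before treatment and treatment lasted 4 weeks, by gavage of 1 mL per 100 g. RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. That text names the honey bee in place of the rat in its account of sequencing, so it is not certain that it describes these libraries.

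The values are FPKM, fragments scaled by transcript length and by the mapped total of the library, in 1 table that the authors deposited. TopHat2, Cufflinks and the rat build Rnor_6.0 are named in the submitters' processing notes. Versions, the annotation release and the use of strand are not given in the sources used here, so overlapping genes and near-identical copies cannot be separated beyond what the deposited values give. FPKM divides by the length and the library total, so a change in a few abundant transcripts moves all other values of that library. The table lists 16987 gene IDs, of which 47 carry a suffix and 238 are at 0 in every library. It holds Ensembl IDs and does not pair them with gene names, and 0 of them matched a symbol in the gene table used here. The gene lists and key genes that had been planned were therefore not tested.

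Depth is not stated. FPKM of genes with few reads take discrete steps, and the ratio of the steps of a pair of libraries gives their relative depth. It was computed from the 2277 IDs with an FPKM below 0.3 in every library and above 0 in at least 3 libraries, with a window of 0.02 on each side on the log2 scale. Relative depth differed by 2.04-fold between the deepest and the shallowest library. A second measure from the same values, called the step score here, places libraries whose low values share the same steps close together. It was the first axis of the centred matrix of the share of IDs in a common step, over all pairs of libraries, and held 44.1% of that matrix's variance. On 12 simulated libraries with 6000 genes and different fragment lengths, the log2 relative depth was recovered within 0.047.

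The 11512 IDs with a mean FPKM of at least 0.5 over the 22 libraries were tested. FPKM values were transformed to log2(FPKM + 1), and a linear model with all 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with expression. All fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. An ID was called when its Benjamini-Hochberg adjusted p was below 0.05 within a comparison. The design gave the comparisons Model with Control, each treatment with Model, and HTJZD with PC-AR. HTJZD with Control and PC-AR with Control were added after the data were examined. For unchanged groups that share the Model libraries, correlations of fold changes were simulated 1000 times and counts of calls 50 times.

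The gene tests, the planned comparisons, the gene lists and a rule for the genes to print were fixed before the data were examined. The rule ranked called genes with a symbol and a mean FPKM of at least 1 in one of the groups compared by their rise and their fall. No ID matched a symbol in the gene table used here, so that condition was dropped. Only the 2 IDs with the largest rise and the 2 with the largest fall per comparison are printed. Measures of whole libraries were added after the data were examined. Each library was placed on the line from the Control mean at 0 to the Model mean at 1, with the library left out of the means. Its distance from a group is the root mean square log2 difference over the tested IDs from the mean of 4 other libraries of that group, averaged over the choices of 4. Differences in these single values between groups were tested by exact permutation, two-sided, with Benjamini-Hochberg adjustment over the 6 comparisons of each measure.

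On simulated data for the 11512 IDs, 71.6% of 67 IDs changed by 1 on the log2 scale were recovered for Model against Control. Recovery of such changes was 79.1% for HTJZD against Model, 71.6% for PC-AR against Model and 77.6% for HTJZD against PC-AR. Of the calls made there, 3.0%, 3.4%, 6.2% and 4.6% were false, in the same order. The simulation drew independent errors with the same spread in all 4 groups. Spread differed between the real groups, so these rates may not hold for the data. Alternatives were other pseudocounts and filters, quantile and median-ratio scaling, fits of only the groups compared, a replicate block, robust variances, library weights, and each library left out in turn. Covariates for the step score and for depth, and fits without doubted libraries, were added after the data were examined. The labels name rats but do not say that each library came from a different rat, so p-values measure the spread between these libraries. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.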

Results

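Liver RNA from 22 libraries was profiled to follow a high-fat diet used to induce hyperlipidemia, and the herbal treatments HTJZD and PC-AR given on top of that diet. There were 5 Control, 5 Model, 6 HTJZD and 6 PC-AR libraries. Between 9906 and 10627 gene IDs had an FPKM of at least 1 in a library, and the top 10 IDs held 24.4% to 28.9% of a library's FPKM sum. Relative depth ran from 0.69 in HTJZD replicate 1 to 1.42 in Control replicate 3. On the log2 scale it averaged 0.230 ± 0.16 in Model, -0.198 ± 0.25 in HTJZD and -0.0167 ± 0.19 in PC-AR (SD, n = 5, 6 and 6). The difference of HTJZD from Model was -0.428 (exact permutation p = 0.0087, adjusted p = 0.052), and that of PC-AR from Model was -0.247 (exact permutation p = 0.039, adjusted p = 0.12), with 6 of 6 libraries of each treatment below the Model mean.

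The number in each library's name runs from 1 to 10 in Control and Model and from 29 to 40 in the treated groups, and no label says what the numbers mark. Low FPKM values followed the same sets in most libraries. The median share of IDs in a common step was 9.2% for pairs within numbers 1 to 10, 13% within 29 to 40 and 6.4% between the sets. The step score was -2.00 ± 0.77 in Model, 0.763 ± 1.5 in HTJZD and 1.93 ± 0.49 in PC-AR (SD, n = 5, 6 and 6), and higher than in Model in both treatments (exact permutation p = 0.011 and 0.0022, adjusted p = 0.022 and 0.013), with 6 of 6 libraries of each above the Model mean. Control replicate 5, at 1.85, and HTJZD replicate 4, at -1.71, went against their set. Control replicate 1 and Model replicate 2 were mixed, with a mean share of 9.8% and 9.4% with numbers 1 to 10 and 11.1% and 9.7% with 29 to 40. Model against Control and HTJZD against PC-AR lie within a set of numbers. Each comparison of a treatment with Model or Control lies across the sets, so a batch that follows the numbers and the treatment cannot be told apart there.

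The first and second principal components held 34.2% and 22.9% of the variance. The 5 Control libraries lay close together, with PC1 scores from -45.3 to -40.9, and the libraries of the other groups were more scattered. In tests added after the data were examined, the root mean square distance of a library from the others of its group was 0.281 ± 0.0053 log2 units in Control and 0.365 ± 0.045 in Model (SD, n = 5 each, exact permutation p = 0.0079, the smallest this design allows, adjusted p = 0.012). It was 0.486 ± 0.13 in HTJZD and 0.487 ± 0.062 in PC-AR (SD, n = 6 each), above Control in both (exact permutation p = 0.0043 and 0.0022, adjusted p = 0.0086 for both). PC-AR lay above Model by 0.122 (exact permutation p = 0.0043, adjusted p = 0.0086), with 6 of 6 libraries above the Model mean, and HTJZD by 0.121 (exact permutation p = 0.056, adjusted p = 0.067), with 5 of 6. In Model, HTJZD and PC-AR every library lay farther from its group than the Control mean. Libraries of a group are measured from one another here. Their distances are therefore not independent, and these p-values are only a guide to a difference in spread.

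**Figure D1:**
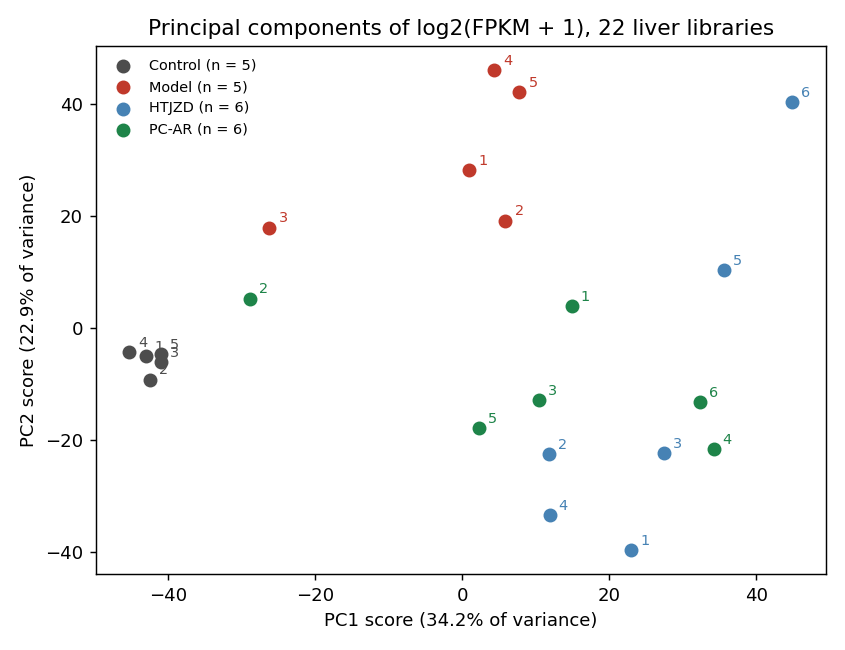
Scores of the 22 libraries on the first and second principal components of log2(FPKM + 1), in percent of variance held, with points coloured by group and numbered by replicate. Control libraries form a tight cluster between -45.3 and -40.9 on PC1, and HTJZD replicate 6, at 44.9 on PC1 and 40.3 on PC2, lies far from most HTJZD libraries.

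The comparison of Model with Control asked what the high-fat diet changed. Of the 11512 IDs tested, 2213 were called, 1255 higher and 958 lower in Model. Among these, 539 were higher and 98 lower by at least 2-fold. ENSRNOG00000013973 rose from a mean FPKM of 2.90 ± 0.555 to 311 ± 363 and ENSRNOG00000002802 from 2.88 ± 1.90 to 91.9 ± 37.1 (SD, n = 5 each). ENSRNOG00000020480 fell from 80.1 ± 5.68 to 12.1 ± 4.83 and ENSRNOG00000017286 from 98.5 ± 41.1 to 26.7 ± 24.7.

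The log2 fold changes of the rises were 5.13 ± 1.21 (SE, limma adjusted p = 0.008) and 4.60 ± 0.57 (adjusted p = 0.00011), and for both IDs all 5 Model libraries lay above every Control library. The falls were -2.69 ± 0.29 (limma adjusted p = 4.7e-05), with 5 of 5 Model libraries below every Control library, and -2.67 ± 0.85 (adjusted p = 0.033), with 3 of 5. The call of ENSRNOG00000017286 was lost without Control replicate 1, 2, 3 or 5 or Model replicate 2 or 4, each left out alone, with adjusted p from 0.052 to 0.11. It was also lost with log2 relative depth as a covariate (log2 fold change -2.3, adjusted p = 0.076) and without both Control replicate 5 and HTJZD replicate 4 (-2.57, adjusted p = 0.071). In 2749 IDs the 2 groups did not overlap, 23.9% of those tested against 0.79% by chance. Direction varied with abundance. Of the called IDs with a mean FPKM of 0.5 to 1, 75.0% were higher in Model, against 45.6% of those at 10 to 100. The share of all calls that were higher was 56.7%, and 46.9% after quantile normalization. Lower IDs were also the majority at a mean FPKM of at least 5 (592 higher and 646 lower), with only these groups in the fit (1980 and 2220) and with library weights (2471 and 2776). The count fell to 1259 without Model replicate 4 and 1306 without Model replicate 5, and it was 4200 when only these groups entered the fit. The main fit shares 1 spread per ID over all 4 groups, and libraries varied least in Control and Model. It can therefore call too few IDs here.

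HTJZD was compared with Model to see what the decoction changed in rats on the diet. There were 3164 called IDs, 1830 higher and 1334 lower, with a median absolute log2 fold change of 0.57. Changes of at least 2-fold were fewer, 189 higher and 215 lower. ENSRNOG00000028896 rose from a mean FPKM of 1.84 ± 1.92 to 46.3 ± 25.1 and ENSRNOG00000015149 from 1.62 ± 1.39 to 46.1 ± 22.9 (SD, n = 5 and 6). ENSRNOG00000043201 fell from 219 ± 28.4 to 36.3 ± 20.7 and ENSRNOG00000022256 from 96.9 ± 111 to 28.5 ± 54.8. ENSRNOG00000043201 was also called lower in PC-AR against Model (log2 fold change -2.04, limma adjusted p = 0.035). ENSRNOG00000015149 and ENSRNOG00000022256 went the same way there without being called (2.33 and -2.9, limma adjusted p = 0.062 and 0.052).

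The log2 fold changes were 4.04 ± 0.70 (SE, limma adjusted p = 0.0015) for ENSRNOG00000028896, with all 6 HTJZD libraries above every Model library, and 3.91 ± 0.79 (adjusted p = 0.0027) for ENSRNOG00000015149, with 5 of 6. They were -2.73 ± 0.56 (limma adjusted p = 0.003) for ENSRNOG00000043201, with 6 of 6 below every Model library, and -2.93 ± 0.93 (adjusted p = 0.025) for ENSRNOG00000022256, with 4 of 6. The last call was lost without Model replicate 4 or 5 or HTJZD replicate 1, 3 or 4, with adjusted p from 0.052 to 0.082. It was also lost with only these groups in the fit (adjusted p = 0.085) and without both Control replicate 5 and HTJZD replicate 4 (0.064). Groups did not overlap in 1484 IDs, 12.9% against 0.43% by chance. With the step score as a covariate the count fell to 155 and none of these 4 IDs was called. Their log2 fold changes were then 3.04, 3.06, -2.34 and -2.69 (limma adjusted p of 0.066, 0.088, 0.081 and 0.18, in the order given here). Over the 3164 IDs the median fold in the direction of the call was 0.57 before and 0.54 after this covariate, and the median SE rose from 0.15 to 0.20. These IDs were chosen in the same data for a difference large against the spread within groups. That choice can lower the slope of any covariate, so the median fold does not decide on the step score.

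The comparison of PC-AR with Model gave 1032 called IDs, 547 higher and 485 lower, of which 41 were higher and 93 lower by at least 2-fold. With only these groups in the fit 582 were called. The main fit shares 1 spread per ID over all 4 groups, while libraries varied least in Control and more in PC-AR. Its p-values for PC-AR against Model can therefore be too low. ENSRNOG00000028896, which also rose with HTJZD, rose from a mean FPKM of 1.84 ± 1.92 to 27.2 ± 29.7 (SD, n = 5 and 6). ENSRNOG00000059447 was listed at 0 in 3 of 5 Model libraries and 1 of 6 PC-AR libraries, and reached 6.29 in Model and 20.5 in PC-AR. ENSRNOG00000019542 fell from 33.1 ± 21.0 to 3.70 ± 1.74 and ENSRNOG00000032240 from 22 ± 15.7 to 2.53 ± 1.46. ENSRNOG00000059447, ENSRNOG00000019542 and ENSRNOG00000032240 were also called in HTJZD against Model. Their log2 fold changes there were 2.06, -2.69 and -1.94 (limma adjusted p of 0.04, 0.0034 and 0.043).

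The log2 fold changes of the rises were 2.65 ± 0.70 (SE, limma adjusted p = 0.03) and 2.36 ± 0.73 (adjusted p = 0.048), with 4 and 5 of 6 PC-AR libraries above every Model library. The falls were -2.72 ± 0.58 (limma adjusted p = 0.019) and -2.41 ± 0.70 (adjusted p = 0.04), with 6 and 4 of 6 below every Model library. Groups did not overlap in 595 IDs, 5.2% against 0.43% by chance. The share of called IDs that were higher ran from 13.5% at a mean FPKM of 0.5 to 1 to 80.3% at 100 or more, and for HTJZD against Model from 25.8% to 67.3%. These comparisons share the Model libraries with that of the diet. Against Control the shares were 41.8% and 53% for PC-AR and 41.3% and 45% for HTJZD. With the step score as a covariate 0 IDs were called by limma, and 1015 had an unadjusted p below 0.05. The median fold of the 1032 IDs went from 0.59 to 0.55 and the median SE from 0.16 to 0.25, but the printed rises fell further, to 1.23 for ENSRNOG00000028896 and 0.92 for ENSRNOG00000059447 (limma adjusted p of 0.67 and 0.78). ENSRNOG00000019542 was then at -2.16 and ENSRNOG00000032240 at -2.52 (adjusted p of 0.56 for both). The 1032 IDs were chosen in the same data too, so their median fold does not decide on the step score. Lower IDs were the majority with no filter (382 higher and 418 lower), with only these groups in the fit (203 and 379), with the replicate block (491 and 740), with library weights (1220 and 1272) and without HTJZD replicates 5 and 6 (1088 and 1228). They were so too without Model replicate 3 (233 and 365), PC-AR replicate 6 (115 and 131) or HTJZD replicate 6 (921 and 945). The count depended on single libraries, those of Control and HTJZD by way of the shared spread and the filter and not of the fold changes. It was 682 and 681 without Control replicates 1 and 4, 343, 598, 43 and 63 without Model replicates 1, 3, 4 and 5, 2260, 686, 81, 497 and 246 without PC-AR replicates 2 to 6, and 1866 without HTJZD replicate 6. The calls of the printed IDs did so too. That of ENSRNOG00000028896 was lost without Model replicate 1, 3, 4 or 5 or PC-AR replicate 4, 5 or 6 (adjusted p from 0.055 to 0.09), and that of ENSRNOG00000019542 without Model replicate 4 or 5 (0.064 and 0.051). That of ENSRNOG00000032240 was lost without Control replicate 1, 4 or 5, Model replicate 1, 4 or 5 or PC-AR replicate 3, 4, 5 or 6 (adjusted p from 0.05 to 0.11). That of ENSRNOG00000059447 was lost without any Control library, Model replicate 1, 3, 4 or 5, PC-AR replicate 3, 4, 5 or 6, or HTJZD replicate 3 or 4 (adjusted p from 0.051 to 0.12). It was also lost at a pseudocount of 0.1 (adjusted p = 0.06) or 3 (0.052), with no filter (0.065), with only these groups in the fit (0.083), with depth as a covariate (0.059) and without both Control replicate 5 and HTJZD replicate 4 (0.063). The log2 fold change of ENSRNOG00000059447 stayed at 2.36 with only these groups and without both libraries, and was 2.48 with depth. ENSRNOG00000028896 was lost with only these groups in the fit (adjusted p = 0.077), and ENSRNOG00000032240 with no filter (0.055), with depth as a covariate (0.051) and without both Control replicate 5 and HTJZD replicate 4 (0.05). The fold changes did not shrink in these fits. That of ENSRNOG00000028896 stayed at 2.65. That of ENSRNOG00000032240 was -2.41 with no filter and without both libraries, and -2.52 with depth.

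**Figure D2:**
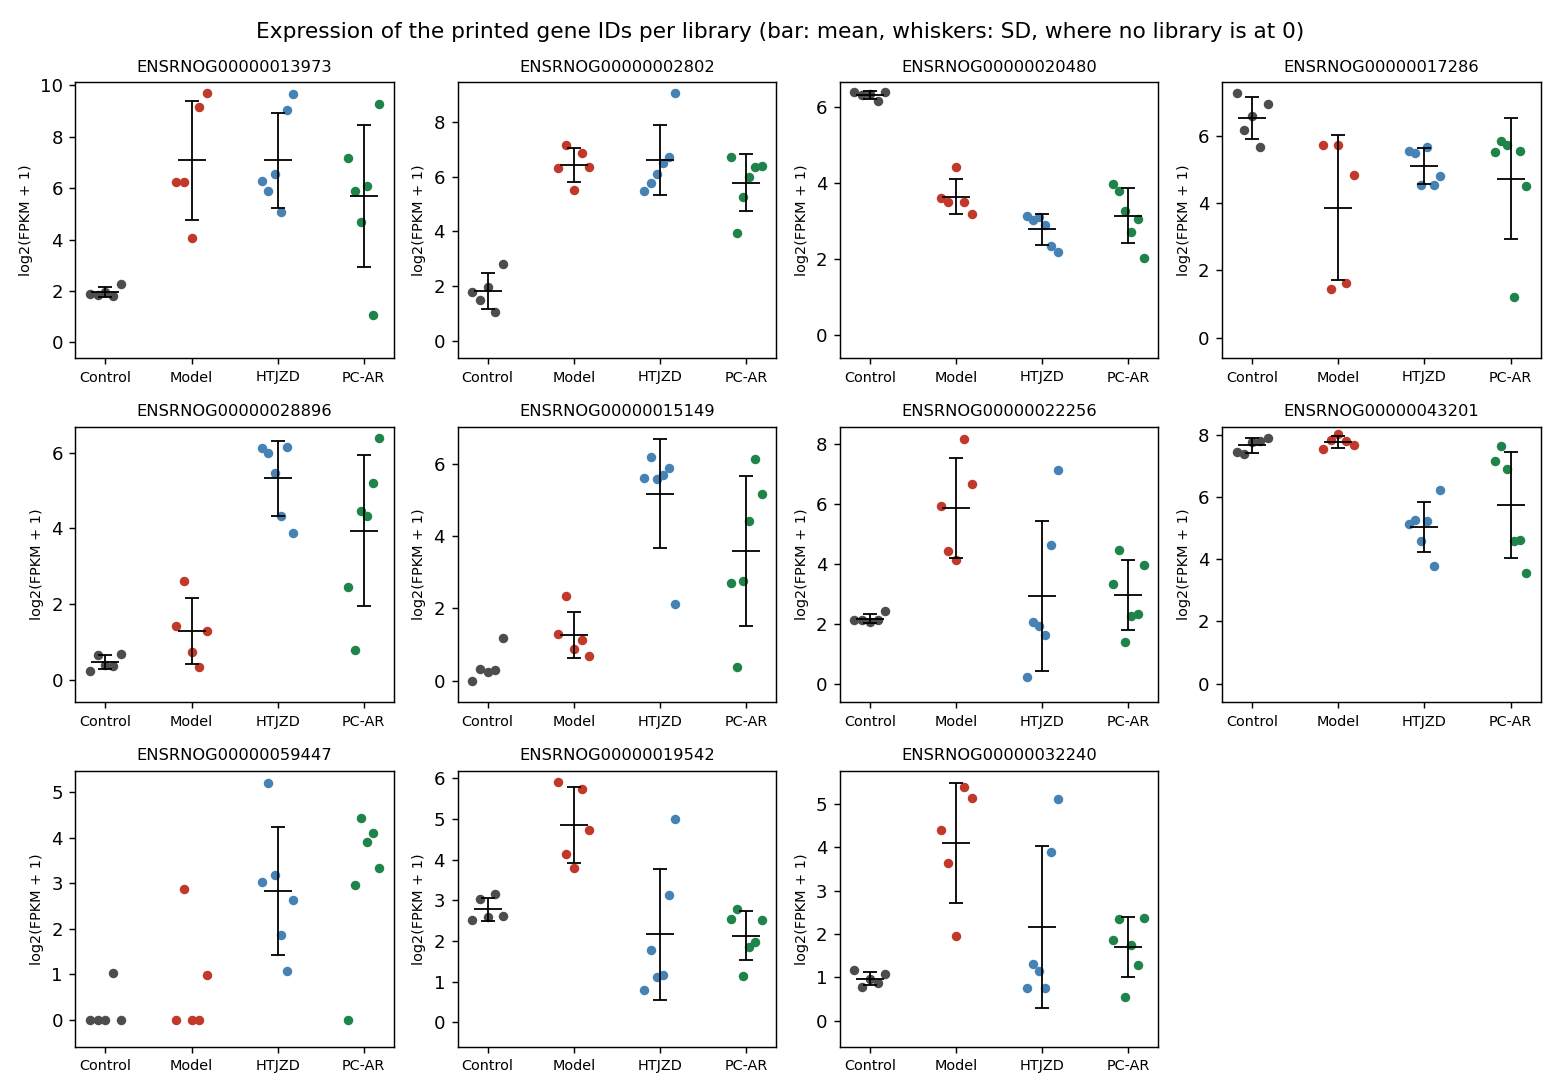
Expression of the 11 printed gene IDs in each library, as log2(FPKM + 1), with 1 point per library; horizontal bars are group means and whiskers SDs, drawn where no library of the group was at 0. ENSRNOG00000028896 lies above every Model library in all 6 HTJZD libraries and in 4 of 6 PC-AR libraries.

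HTJZD and PC-AR were compared directly, within 1 set of library numbers. No ID was called by limma (0 of 11512), and the lowest adjusted p was 0.529. At an unadjusted p below 0.05 there were 883 IDs, 397 higher and 486 lower in HTJZD. ENSRNOG00000028896 differed by 1.39 on the log2 scale (adjusted p = 0.65) and ENSRNOG00000015149 by 1.58 (adjusted p = 0.65), each with 5 of 6 HTJZD libraries above the PC-AR mean. ENSRNOG00000043201 differed by -0.70 (adjusted p = 0.75), with 5 of 6 below it. Groups did not overlap in 16 IDs, 0.1% against 0.22% by chance. A p that misses the threshold does not show that the treatments act alike.

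The responses to the treatments, each measured against Model, resembled one another. Of the called IDs, 503 were higher with both and 373 lower with both, against 87.0 and 56.2 for independent lists, and 0 were called in opposite directions. Across IDs, which are not independent replicates, the fold changes had a Pearson r of 0.87. Both comparisons use the Model libraries, and simulated unchanged groups gave an r of 0.39 (95% of simulations from -0.11 to 0.73). They also gave 0 shared calls, but with no group changed few IDs can be called, so this 0 does not test the overlap. The covariance was 0.179 against 0.0211 in the simulation (-0.00431 to 0.0534), and the difference was 0.158. With the Model libraries split so that no library was shared, r had a median of 0.69 (0.52 to 0.80 over 20 splits), and the median count of shared IDs was 1 (0 to 128), with 2 or 3 Model libraries in each comparison. With the step score as a covariate 0 IDs were shared by limma's calls, and 791 had an unadjusted p below 0.05 in both with the same direction. The 876 shared IDs became 298, 504, 39 and 58 without Model replicates 1, 3, 4 and 5, 1889, 77, 443 and 221 without PC-AR replicates 2, 4, 5 and 6, and 1706 without HTJZD replicate 6.

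Diet-changed IDs were then followed under treatment. The lists of diet and treatment share the Model libraries, which by itself adds reversals and removes changes further the same way. The counts for independent lists are therefore no test of reversal. With PC-AR, 178 of the 1255 IDs that were higher in Model were called lower (52.9 for independent lists). Of the 958 that were lower, 59 were called higher (45.5), 237 reversed in all. Another 20 changed further the same way, 5 higher (59.6) and 15 lower (40.4). With HTJZD, 200 were called lower (145.4) and 136 higher (152.3), 336 reversed in all. Another 162 changed further the same way, 37 higher (199.5) and 125 lower (111). Of the IDs that were lower in Model, 136 thus rose with HTJZD and 125 fell further. Among the reversed IDs, ENSRNOG00000022256 went from 3.55 ± 0.473 in Control (SD, n = 5) to 96.9 in Model and 28.5 with HTJZD. ENSRNOG00000019542 went from 5.97 ± 1.44 to 33.1 in Model and 3.70 with PC-AR, and ENSRNOG00000032240 from 0.972 ± 0.21 to 22 and 2.53. Both were also called lower with HTJZD, at 7.37 ± 11.8 and 8.6 ± 13.3 (SD, n = 6). For each, 5 of 6 HTJZD libraries lay below the Model mean. ENSRNOG00000020480, which the diet lowered, was lower still with HTJZD, at 6.15 ± 1.84 (SD, n = 6), a log2 fold change of -0.85 from Model (limma adjusted p = 0.029), with 6 of 6 HTJZD libraries below the Model mean.

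The fold changes of diet and HTJZD had an r of -0.20 across IDs and those of diet and PC-AR an r of -0.42. Leaving out 1 library, the first ranged from -0.31 (without HTJZD replicate 6) to -0.12 (without HTJZD replicate 4). The second ranged from -0.52 (without Model replicate 3) to -0.31 (without PC-AR replicate 2). Simulated unchanged groups that share the Model libraries gave -0.48 for both (95% of simulations from -0.79 to 0.02 and from -0.78 to 0). The simulation held no diet effect, whereas 2213 IDs were called for the diet here. A diet effect changes the r that shared libraries give, so the observed values cannot be judged against -0.48. IDs are not independent replicates. Covariances were -0.0528 and -0.0941, against -0.0211 (-0.0487 to 0.000511) and -0.0210 (-0.0440 to -1.55e-05) in the simulation, and both lay outside these intervals. The simulations of calls gave 0 reversed IDs for either treatment, but with no group changed few IDs can be called, so this 0 does not test reversal. With the Model libraries split, the median r was -0.13 (-0.34 to 0.11) for HTJZD and -0.30 (-0.53 to -0.06) for PC-AR, and the median count of reversed IDs fell to 19 and 0.5, with 2 or 3 Model libraries in each comparison. With the step score as a covariate 25 and 0 IDs were reversed by limma's calls, and for PC-AR 415 had an unadjusted p below 0.05 in both comparisons in opposite directions. The 336 IDs reversed by HTJZD became 220 and 221 without Control replicates 2 and 4, 170, 114 and 149 without Model replicates 1, 4 and 5, and 208, 213, 206 and 953 without HTJZD replicates 1, 3, 4 and 6. The 237 reversed by PC-AR became 124, 132, 141, 124 and 135 without Control replicates 1 to 5, 60, 11 and 12 without Model replicates 1, 4 and 5, 142, 27, 105 and 78 without PC-AR replicates 3 to 6, and 604 without HTJZD replicate 6. The 162 IDs that HTJZD changed further the same way became 105, 103 and 94 without Control replicates 1, 2 and 4, 79, 93, 64 and 72 without Model replicates 1, 2, 4 and 5, and 270 without PC-AR replicate 2. The 20 of PC-AR became 9, 10, 9, 8 and 12 without Control replicates 1 to 5, 8, 13, 5, 3 and 3 without Model replicates 1 to 5, 147, 10, 3, 13 and 5 without PC-AR replicates 2 to 6, and 12, 13 and 35 without HTJZD replicates 2, 3 and 6. With the step score as a covariate these counts were 7 and 0 by limma's calls, and for PC-AR 35 IDs had an unadjusted p below 0.05 in both comparisons in the same direction.

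**Figure D3:**
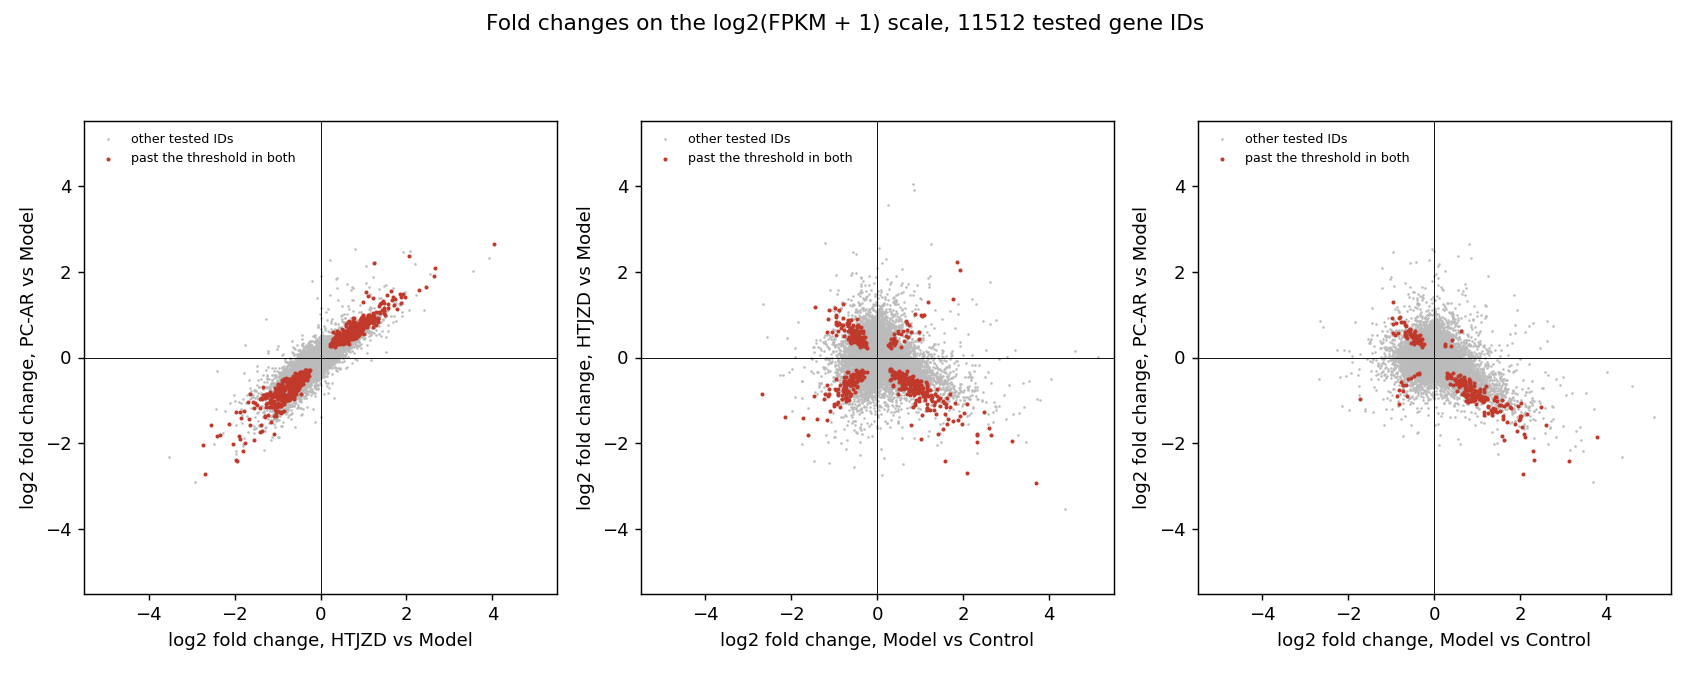
Log2 fold changes of 11512 IDs for PC-AR against HTJZD, each measured from Model, and for each treatment against the diet, with IDs called in both comparisons in red. The treatments lie along a rising line (r = 0.87), and the relation of diet and treatment is weaker (r = -0.20 for HTJZD and -0.42 for PC-AR), with Model libraries shared in every panel.

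Whole libraries did not lie nearer to Control by a detectable amount, in tests added after the data were examined. On the line from Control at 0 to Model at 1, Model libraries lay at 0.942 ± 0.31 (SD, n = 5), HTJZD at 0.809 ± 0.41 and PC-AR at 0.668 ± 0.19 (SD, n = 6 each). The differences from Model were -0.133 (exact permutation p = 0.56, adjusted p = 0.56) and -0.274 (exact permutation p = 0.1, adjusted p = 0.15), with 4 of 6 HTJZD and 6 of 6 PC-AR libraries below the Model mean. The HTJZD difference ranged from -0.267 without HTJZD replicate 6 to -0.048 without Model replicate 4. Without HTJZD replicates 5 and 6 it was -0.379 (exact permutation p = 0.063). These were left out as the HTJZD libraries farthest from their group. They also lay highest of that group on this line, at 1.12 and 1.48. Leaving them out must move HTJZD towards Control, so this p is no test of such a move. Without Model replicate 3 the PC-AR difference was -0.317 (exact permutation p = 0.033). The distance from the Control mean was 0.607 ± 0.12 in Model, 0.760 ± 0.12 in HTJZD and 0.653 ± 0.13 in PC-AR (exact permutation p against Model = 0.069 and 0.54, adjusted p = 0.1 and 0.54), with 6 and 4 of 6 libraries above the Model mean. The HTJZD difference of 0.153 passed 0.05 without Model replicate 4 or 5 (0.179 and 0.177, exact permutation p = 0.048 for both) or HTJZD replicate 2 or 4 (0.178 and 0.176, p = 0.04 for both). It also did so with a mean FPKM of at least 5 (0.193, exact permutation p = 0.024) and without both Control replicate 5 and HTJZD replicate 4 (0.174, p = 0.04). Without Model replicate 3 it was 0.105, and the p over single libraries left out reached 0.17. That of PC-AR, 0.046, was -0.002 without Model replicate 3. Against Control, a comparison added after the data were examined, 4904 IDs were called for HTJZD and 3257 for PC-AR. With the step score as a covariate these counts were 3338 and 218, with 4791 and 2530 IDs at an unadjusted p below 0.05. The median fold of the 3257 IDs went from 0.60 to 0.57 and the median SE from 0.16 to 0.23. As these IDs were chosen in the same data, their median fold does not decide on the step score. Of the IDs not called for the diet, HTJZD changed 2666 against Model, 84.3% of its calls, and PC-AR 775, 75.1% of its calls. Among all tested IDs, 9299 were not called for the diet, 80.8%.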

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

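All tests of explanations in this part were chosen after the pattern was seen, and the pair that used IDs with a mean FPKM of at least 10 was set out before its result was known. Within each group, 21 measures were searched for a library far from the others, 84 searches in all, of which chance gives about 1 in 20 for normally distributed values. There were 14 such cases, in 9 libraries. Most were untransformed FPKM of the printed IDs, which were picked for large fold changes, so that rate need not hold for these cases.

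Several of them are HTJZD replicate 6. Its FPKM was 522 for ENSRNOG00000002802, where the other HTJZD libraries lay between 43.2 and 104. It was 3.37 for ENSRNOG00000015149 (others 46.2 to 71.6), 139 for ENSRNOG00000022256 (0.19 to 24.0) and 30.8 for ENSRNOG00000019542 (0.734 to 7.78). PC-AR replicate 6 had an FPKM of 617 for ENSRNOG00000013973, against 1.08 to 142 in the other PC-AR libraries. HTJZD replicate 2 had 35.7 for ENSRNOG00000059447, against 1.08 to 8.10. Model replicate 2 had 6.29 for the same ID (others 0 to 0.970) and 4.03 for ENSRNOG00000015149 (0.592 to 1.46). Model replicate 3 had 20.5 for ENSRNOG00000020480 (8.10 to 11.2). Control replicate 5 had 1.27 for ENSRNOG00000015149 (0 to 0.25) and 4.38 for ENSRNOG00000022256 (3.19 to 3.42), and Control replicate 4 had 1.05 for ENSRNOG00000059447, which was at 0 in the other Controls. PC-AR replicate 1 had a step score of 0.97 (1.90 to 2.31), and PC-AR replicate 2 lay 0.605 log2 units from its group (0.433 to 0.494).

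HTJZD replicate 6 lay 0.725 log2 units from its group over all tested IDs. Low depth is argued against, since among IDs with a mean FPKM of at least 10 the distance was 0.740, against at most 0.542 for the other HTJZD libraries (SD 0.079). On a mislabelled Model library the values differ. The distance of 0.597 from the Model mean, where Model libraries reach 0.438, goes against it. Yet that distance is smaller than the one from its own group. On the line from Model to the treated libraries HTJZD replicate 6 lay at 0.28, within the Model libraries' -0.15 to 0.42, as did PC-AR replicate 2 at 0.19. A mislabelled library is therefore not excluded. A difference in the animal or the sample stays open, and no biological explanation was tested.

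HTJZD and PC-AR libraries differed from Model in the same direction. Depth accounted for -6.87% of the difference over the 876 shared IDs, by the slope within groups (95% interval -24.8 to 11.1). These IDs were chosen in the same data for a difference that is large against the spread within groups. That choice can lower the slope of any covariate, so such shares do not decide on depth or the step score. With depth as a covariate in the fit of all IDs 698 were shared, and 1085 after quantile normalization, which argues against depth and scaling as the whole cause. The step score accounted for 7.76% (-26.0 to 41.5), but for 43.7% (-19.6 to 107) without Control replicate 5 and HTJZD replicate 4, so it stays open and rests on these libraries. On the line from Model to the treated libraries, Control replicate 5 lay at -0.02 relative to the other Controls and HTJZD replicate 4 at 1.31, where the other 11 treated libraries averaged 0.92. With 0 treated libraries numbered in the Model range, a batch that follows the library numbers and an effect common to both treatments cannot be told apart.

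Model, HTJZD and PC-AR libraries varied more within their group than Control libraries. Step scores spanned 4.53 in Control, more than the 1.84, 4.10 and 1.34 of Model, HTJZD and PC-AR. Without Control replicate 5 they spanned 1.91, still above Model and PC-AR but below HTJZD. A narrower span in Control thus does not account for Model and PC-AR, while the library property behind the score stays open for HTJZD. Among IDs with a mean FPKM of at least 10, the least distant library outside Control still lay 1.14 times as far from its group as the farthest Control library, which argues against low depth. The diet, given to all 3 groups, is a biological difference named by the design and stays open as a hypothesis, as does a difference in handling. PC-AR libraries lay farther from their group than Model libraries on the same diet (0.487 and 0.365, exact permutation p = 0.0043, adjusted p = 0.0086, 6 of 6 above the Model mean). The diet alone leaves this out, but distances within a group depend on one another, so the p is only a guide.

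Other splits of the same libraries, 100 per comparison with the real one included, gave as many calls as Model against Control in 1 (highest other 4, real 2213), HTJZD against Control in 1 (3469, real 4904) and PC-AR against Control in 1 (2237, real 3257). Only the real split gave as many there, which argues against chance alone. For the treated groups this leaves a batch that follows the library numbers open. For HTJZD against Model it was 2 (highest other 4150, real 3164) and for PC-AR against Model 3 (1834, real 1032). Few splits gave as many, but another split gave more calls than the real one. The shares were not adjusted over the comparisons, so neither chance nor the library numbers can be excluded there. The split with 4150 calls placed HTJZD replicate 6 with the 5 Model libraries, and that with 1834 exchanged Model replicate 2 with PC-AR replicate 2. For HTJZD against PC-AR all 100 splits gave as many as the 0 real calls, which any split must, so this says nothing about chance. The highest other count was 750, and a split with so many more calls than the real one points to a structure of the samples, which was not tested. That split placed PC-AR replicates 1, 4 and 6 with HTJZD replicates 3, 5 and 6. They lay at 0.73 to 1.48 on the line from Control to Model, and the other treated libraries at 0.39 to 0.63.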

How the results depend on the processing

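Covariates, fits without 2 libraries, the comparisons of treated groups with Control, and positions and distances of libraries were added after the data were examined. Of the values recomputed, 1223 kept their side of the threshold or stayed within 1.5 times, 170 counts or correlations moved further, 67 calls were lost, 7 were gained and 1 changed sign. The cause was not tested unless stated. The gene lists were not run, for want of gene names. Depth is known only in relative terms, which limits statements on low genes.

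With only the groups compared in the fit, Model against Control gave 4200 calls, HTJZD against Model 2737 and PC-AR against Model 582. The main fit shares 1 spread per ID over groups of unequal spread. This can lower counts for Model against Control and raise those of treatments against Model. A mean FPKM of at least 5, which tests fewer IDs, gave 1238 for Model against Control and 199 and 118 reversed IDs for HTJZD and PC-AR. Library weights gave 5247, 5494 and 2492 calls for Model against Control, HTJZD against Model and PC-AR against Model, 1999 and 1154 reversed IDs, 710 and 205 changed further the same way, and 2385 shared IDs. The step score as a covariate gave 155 calls for HTJZD against Model and 0 for PC-AR against Model. It gave 3338 for HTJZD against Control and 218 for PC-AR against Control. There were then 25 and 0 reversed IDs, 7 and 0 changed further the same way, and 0 shared IDs. For PC-AR against Control the median fold went from 0.60 to 0.57 and the median SE from 0.16 to 0.23. That fold is over IDs chosen in the same data, so it does not decide on the step score. Depth as a covariate gave 150 IDs reversed by PC-AR and 67 changed further the same way by HTJZD. Without Control replicate 5 and HTJZD replicate 4 there were 626 calls for PC-AR against Model, 152 and 138 reversed IDs, 87 and 9 changed further the same way, and 473 shared IDs. Without HTJZD replicates 5 and 6 there were 4787 calls for HTJZD against Model and 2316 for PC-AR against Model. Reversed IDs were then 1358 and 894, and shared IDs 2132. HTJZD replicates 5 and 6 were left out as the farthest from their group, which lowers the spread and can add calls. With the Model libraries split, medians were 19 and 0.5 reversed IDs and 1 shared ID, with 2 or 3 Model libraries per comparison.

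The replicate number pairs no libraries. Same-numbered libraries had correlations of their deviations from -0.43 to 0.44, and the best match had the same number for 3 of 22. With the replicate block there were 2243, 3060, 1231 and 0 calls in the planned comparisons, 461 and 482 reversed IDs and 964 shared IDs.

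Without 1 library at a time, calls ranged from 1259 to 2703 for Model against Control, 2229 to 4335 for HTJZD against Model, 43 to 2260 for PC-AR against Model, 0 to 1 for HTJZD against PC-AR (1 without PC-AR replicate 5), 4237 to 5033 for HTJZD against Control and 2344 to 4057 for PC-AR against Control. Reversed IDs ranged from 114 to 953 for HTJZD and 11 to 604 for PC-AR, and shared IDs from 39 to 1889. The position on the diet line, relative to Model, ranged from -0.267 to -0.048 for HTJZD and from -0.330 to -0.193 for PC-AR, whose exact permutation p was 0.033 to 0.26 and passed 0.05 only without Model replicate 3 (-0.317). The distance from Control of PC-AR less that of Model ranged from -0.002, without that library, to 0.09, without PC-AR replicate 2. Counts by direction moved too. IDs lower in Model, 958 with all libraries, were 509 without Model replicate 4. IDs lower with HTJZD than in Model, 1334 with all libraries, were 2004 without HTJZD replicate 6. Counts of all calls, of reversed IDs and of shared IDs moved by over 1.5 times without the following libraries. Model against Control gave 1259 and 1306 without Model replicates 4 and 5. PC-AR against Model gave 682 and 681 without Control replicates 1 and 4, 343, 598, 43 and 63 without Model replicates 1, 3, 4 and 5, 2260, 686, 81, 497 and 246 without PC-AR replicates 2 to 6, and 1866 without HTJZD replicate 6. Reversal by HTJZD gave 220 and 221 without Control replicates 2 and 4, 170, 114 and 149 without Model replicates 1, 4 and 5, and 208, 213, 206 and 953 without HTJZD replicates 1, 3, 4 and 6. Reversal by PC-AR gave 124, 132, 141, 124 and 135 without Control replicates 1 to 5, 60, 11 and 12 without Model replicates 1, 4 and 5, 142, 27, 105 and 78 without PC-AR replicates 3 to 6, and 604 without HTJZD replicate 6. Shared IDs numbered 298, 504, 39 and 58 without Model replicates 1, 3, 4 and 5, 1889, 77, 443 and 221 without PC-AR replicates 2, 4, 5 and 6, and 1706 without HTJZD replicate 6.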

Other observations

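The splits of the Model libraries were chosen as a test after the shares in all libraries were seen. A hypothesis on return towards Control was tested. Of the 1255 IDs that the diet raised, 79.8% lay below Model with HTJZD and 86.5% with PC-AR, while 49.9% and 61.5% of the 958 that it lowered lay above Model. These comparisons share the Model libraries, so the Model libraries were split in 20 ways. Raised IDs then lay towards Control in a median of 75.7% with HTJZD (50.9 to 88.9) and 82.4% with PC-AR (66.7 to 91.1), and lowered IDs in 39.7% (25.2 to 57.7) and 49.0% (36.7 to 78.9). The share was larger for raised IDs in all 40 cases over both treatments, which use the same libraries again and as few as 9 raised and 8 lowered IDs. A shift of all IDs of the same abundance was argued against by a test set out before its result was seen. Matched IDs not called for the diet went the other way, at -16.8% of the excess with HTJZD and -25.6% with PC-AR. A one-sided return, in which treatment may act mainly on what the diet raised, remains a hypothesis, since a batch that follows the library numbers cannot be told apart from treatment.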
